A study of Mus musculus with 11 samples.

How the data were processed

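Gene expression was measured in 11 libraries of mouse embryonic dorsal telencephalon. Polyadenylated RNA was sequenced from stranded libraries as single-end reads of 75 bases, per the labels' protocols. The deposited files hold raw read counts per gene, written by featureCounts 2.0.1 with reversely stranded counting over exons, per the file headers. Other tools named in the submitters' processing notes were CASAVA 1.9, FastQC 0.11.8, HISAT2 2.2.1, SAMtools 1.9 and deepTools 3.3.0, with the genome build GRCm38. The annotation release behind the counts was not given in the sources used here. Whether reads that map to several places were counted was not given either, so counts of pseudogenes, paralogs and ribosomal protein genes are uncertain.

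Each file held 46078 gene identifiers, of which 45143 (97.971%) had a symbol in the reference name table. The 935 identifiers without a symbol held 0.1117% of all counts and kept their identifier. No entry lacked a gene (0 of 46078). Library totals ran from 16527551 counts in heterozygote replicate 2 to 26658718 in heterozygote replicate 1, and from 18266535 to 20895655 at E15.5. A count of 0 allowed a level of up to 3 counts, which was 0.113 to 0.182 CPM depending on the library. Such floors cover counting error only, since reads without molecular identifiers are not independent molecules.

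Groups came from the sample titles. The gain comparison set 3 libraries of sorted cells electroporated with L3mbtl3 against 3 electroporated with the empty GFP plasmid. The loss comparison set 2 libraries labelled L3mbtl3 knockout against 3 controls, made up of 2 labelled heterozygote and 1 labelled wild-type, as the series' design counts them. Nothing in the labels says that the libraries came from separate embryos, so p-values measure only the spread between these samples. By Xist and Y-linked counts the 2 libraries labelled knockout differed in sex and so came from different embryos. The same holds for gain replicate 2 against gain replicates 1 and 3. Spread between libraries of the same label and sex may be technical. Libraries of a group differed by more than sampling noise. Their chi-square per degree of freedom was 29.7 to 94.4 among the GFP controls, 9.60 to 14.4 among the gain libraries, 2.60 to 3.79 among the E12.5 controls and 11.2 between the libraries labelled knockout. Sex-linked genes entered these values. The libraries labelled knockout differed in sex, as did some gain libraries, while the GFP and E12.5 controls were all male. The part due to sex was not separated.

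Counts were tested with edgeR 4.0.16 (robust quasi-likelihood fit, TMM factors, filterByExpr) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over the genes tested. A gene was called, and said to have risen or fallen, at an adjusted p under 0.05. CPM values carry the TMM factors of their comparison and are given as mean ± SD with n libraries. EdgeR's test gives no standard error. The SE beside an edgeR fold change is its absolute log2 value divided by the square root of the test's F statistic. Gene lists were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01, and adjusted over the lists with at least 3 tested members. The lists covered apical progenitors, intermediate progenitors, proneural factors and their reported targets, the Notch pathway, pan-neuronal genes, deep-layer neurons, upper-layer neurons, Cajal-Retzius cells, ventral telencephalon and GABAergic neurons, astrocyte and oligodendrocyte lineages, cortical hem and Wnt signalling, choroid plexus, G1 and S phase, G2 and M phase, PRC1 subunits, PRC2 subunits, the MBT-domain family with reported L3mbtl3 partners, Hox genes, developmental regulators of other regions and tissues, microglia and macrophages, endothelial cells and pericytes, erythroid cells, meninges and mesenchyme, immediate early and dissociation response, interferon response, p53 response and cell death, hypoxia and glycolysis, ribosomal proteins, mitochondrially encoded mRNAs and replication-dependent histones. Hox genes were tested in neither comparison (0 of 39 passed the count filter), and the developmental regulators were not tested as a list in the gain comparison (2 of 51 passed).

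The tests, the lists, the alternative settings and the rule for named genes were chosen before the data were examined. The rule named L3mbtl3, the 8 called coding genes per direction with the largest fold change, a mean log2 CPM of at least 1 and no overlap between arms, and up to 4 called members of each list. Where a list had no called member, the 2 members with the smallest p were given as values. A fixed set of neurogenesis genes was added, and, where fewer than 10 genes were called, the 10 with the smallest p. The values of 3 single genes that the rule or a test named are not reported here, though counts of called genes include them. Xist and Y-linked genes served only as a check of embryo sex. By these counts the 3 GFP controls and gain replicate 2 were male, gain replicates 1 and 3 were female, and at E12.5 only the library labelled knockout replicate 2 was female.

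Both comparisons were also set against each other by correlation across genes, by testing the called genes of each as sets in the other, and by a test of the difference of effects in a single fit of all 11 libraries. Alternative settings of that kind were DESeq2 1.42.0, voom with sample quality weights, other scaling factors and count filters, all libraries in 1 fit, a fold change threshold, the replicate number as a block, each library left out in turn, other codings of genotype, camera with an estimated correlation, and fry. A term for embryo sex, male libraries only, a surrogate variable from sva 3.50.0 and a per-library offset for exonic length (loess span 0.3) were added after seeing the data. No control was female. With a sex term, as with male libraries only, the arm effect therefore rests on gain replicate 2 or on knockout replicate 1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

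The scripts were tested on simulated data with known fold changes. Changes were set only in genes with a mean log2 CPM of at least 1. Each gene was drawn independently, so trends shared between genes, such as the length trend, were not simulated. In the simulated gain comparison (14344 genes tested), edgeR recovered 3 of 67 genes changed by 0.5 on the log2 scale, 31 of 67 changed by 1 and 63 of 65 changed by 2, with 10 unchanged genes called. DESeq2 recovered 14 of 67, 51 of 67 and 65 of 65 there, with 45 unchanged genes called. In the simulated loss comparison (16169 genes tested), edgeR recovered 57 of 67, 65 of 67 and 66 of 66, with 17 unchanged genes called. The CD15-positive cells that the series' design mentions were not analysed here.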

Results

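Messenger RNA was sequenced from the mouse dorsal telencephalon, the part of the embryonic forebrain that forms the neocortex. For the gain comparison, a GFP plasmid (pCIG2), empty or carrying L3mbtl3, was electroporated into the embryonic brain at E12.5, and GFP-positive cells were sorted at E15.5. It held 3 libraries per arm, with totals of 18266535 to 20863979 counts in the GFP controls and 18951220 to 20895655 in the gain libraries. For the loss comparison, E12.5 tissue gave 2 libraries labelled L3mbtl3 knockout and 3 controls, with totals of 16527551 to 26658718 counts. The controls were 2 libraries labelled heterozygote and 1 labelled wild-type. The series' title ties L3mbtl3 to the Polycomb complex PRC1, to cortical neurogenesis and to proneural genes, and the comparisons ask which transcripts differ with more or less L3mbtl3.

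L3mbtl3 encodes a chromatin-associated protein with MBT domains (ENSMUSG00000039089, GRCm38 chromosome 10, 26274468 to 26375185). It was higher after electroporation of L3mbtl3, at 1132 ± 286 CPM against 50.4 ± 4.82 in the GFP controls (SD, n = 3 each). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment it rose by 4.49 (log2, SE 0.217, adjusted p = 0.00136), and it was higher in 3 of 3 gain libraries. Without GFP control replicate 2 the fold change was 4.42 and the call was lost (edgeR adjusted p = 0.0539). At E12.5 L3mbtl3 was not lower in the libraries labelled knockout. It measured 76.1 ± 2.41 CPM there (n = 2) and 63.4 ± 1.70 in the controls (n = 3), and rose by 0.27 (log2, SE 0.0539, edgeR adjusted p = 0.0128). The call was lost without knockout replicate 2 (0.23, edgeR adjusted p = 0.0550). The heterozygote libraries had 61.5 and 63.9 CPM and the wild-type library 64.7 CPM. Counts summed over all exons of a gene do not show whether an exon was deleted, and the groups are therefore named below by their labels.

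**Figure D1:**
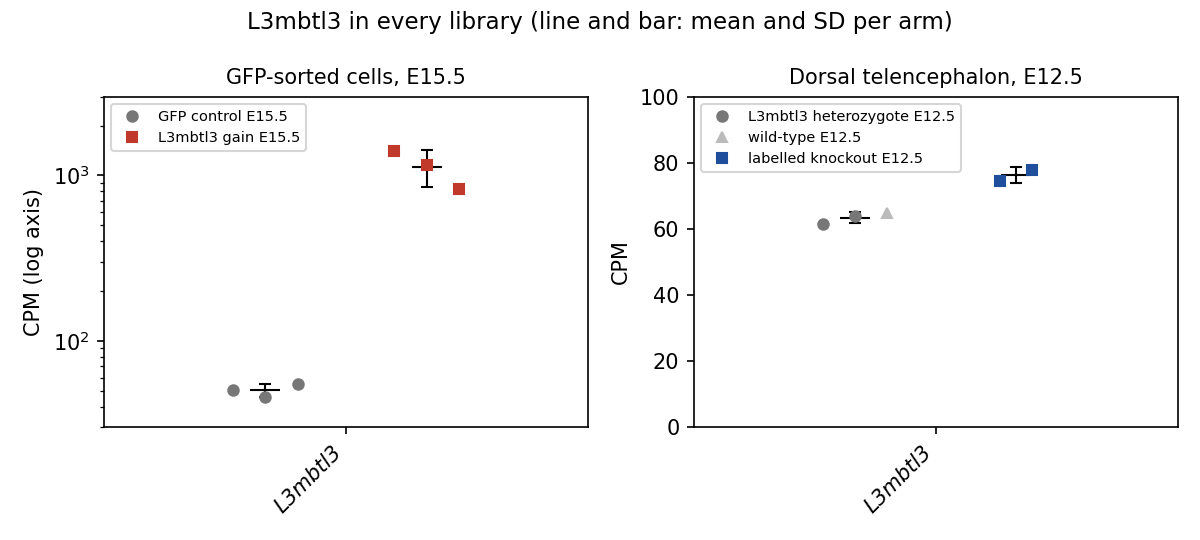
L3mbtl3 in CPM per library, for GFP-sorted cells at E15.5 (left, log axis) and dorsal telencephalon at E12.5 (right, linear axis). Points are libraries, and the line and bar give the mean and SD per arm. The gain libraries lie above all GFP controls, and both libraries labelled knockout lie above all 3 controls.

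In the sorted E15.5 cells, genes of microglia and of blood vessels were lower in the L3mbtl3 gain libraries, while markers of cortical progenitors and neurons showed no called change in the main fit. Of 14 tested microglia and macrophage genes 13 were lower, with a median of -2.14 (log2), and of 12 endothelial and pericyte genes 12 were lower, with a median of -1.22. Csf1r, the growth factor receptor that microglia depend on, measured 1.47 ± 0.931 CPM against 8.27 ± 3.19 in the GFP controls (n = 3 each), with a fold change of -2.48 (log2, SE 0.502). P2ry12, a purinergic receptor of microglia, had a fold change of -2.53 (SE 0.465). Cdh5, the cadherin of endothelial junctions, stood at -2.13 (SE 0.431), and Cldn5, a tight junction protein of brain vessels, at -1.63 (SE 0.371). These 4 genes did not pass edgeR's test over all genes (adjusted p of 0.457 for Csf1r, P2ry12 and Cdh5, and 0.463 for Cldn5). Their levels in sorted cells were low. Cldn5 had 36, 40 and 54 counts in the GFP controls and 18, 11 and 13 in the gain libraries, against 603 to 867 in the E12.5 libraries. Whether these transcripts came from electroporated cells or from other cells in the sort was not tested. Adjusted over the list alone, 11 of the 14 microglial genes and 3 of the 12 endothelial genes fell, against 0 and 0 over all genes tested. Both lists passed camera (adjusted p = 7.04e-10 and 2.77e-07). The calls were lost with an estimated correlation, at adjusted p = 0.671 for microglia and adjusted p = 0.183 for endothelial cells. The libraries also differed within an arm in other cell markers. Dlx2, a homeobox gene of the ventral telencephalon, had 134, 50.1 and 2.36 CPM in the 3 GFP controls and 34.8, 26.4 and 1.33 CPM in the 3 gain libraries.

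Genes of G1 and S phase and ribosomal protein genes were lower as lists in the gain libraries. G2 and M phase genes were not called as a list by the main test (21 of 22 lower, median -0.36, camera adjusted p = 0.454), but were called lower with DESeq2, voom with quality weights, the replicate number as a block, a surrogate variable and without GFP control replicate 3. All 22 G1 and S phase genes were lower, with a median of -0.30 (log2), among them Chaf1b, a chromatin assembly factor subunit (-0.46, SE 0.103), and Mcm7, a subunit of the replicative helicase (-0.17, SE 0.0936). Of 78 ribosomal protein genes 68 were lower, with a median of -0.14, while Rpl21 stood at 0.63 (SE 0.258) and Rpl26 at -1.39 (SE 0.503). No member of either list passed edgeR's test, over all genes or adjusted over the list alone. Camera gave adjusted p = 0.0253 for G1 and S phase and adjusted p = 0.000232 for ribosomal proteins. With an estimated correlation both had an adjusted p = 0.961. Both calls were also lost with a term for embryo sex (medians of -0.22 and -0.08) and with male libraries only. In each of these fits the gain effect rests on gain replicate 2, since 2 of the 3 gain libraries but no GFP control were female. The G1 and S phase call was lost when libraries were scaled by their totals only, without GFP control replicate 1, where the median was 0.04, and without GFP control replicate 2 (-0.33), gain replicate 1 (-0.32) and gain replicate 3 (-0.24), and without GFP control replicate 3 the median was -0.55. The ribosomal call was lost without GFP control replicate 3 (-0.01) and gain replicate 1 (-0.09), and without GFP control replicate 1 the median was -0.24.

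Genes of the neurogenic programme showed no called change in sorted cells in the main fit. Neurog2, the main proneural factor of the cortex, measured 189 ± 15.3 CPM against 170 ± 24.6 (n = 3 each), with a fold change of 0.15 (log2, SE 0.125). Eomes, the transcription factor of intermediate progenitors, stood at 0.19 (SE 0.137) and Tbr1, a factor of deep-layer neurons, at -0.10 (SE 0.166). The apical progenitor factors Pax6 and Sox2 stood at 0.18 (SE 0.318) and -0.68 (SE 0.542), and the proneural factor Neurog1 at 0.50 (SE 0.333). Among Notch genes, the effectors Hes1 and Hes5 had fold changes of -0.13 (SE 0.579) and -0.21 (SE 0.443), the ligand Dll1 -0.05 (SE 0.212), and Rbpj, the DNA-binding factor of the pathway, 0.38 (SE 0.185). Each of these 10 genes missed edgeR's threshold, with adjusted p values from 0.588 for Rbpj to 0.945 for Dll1. Sox2 ranged from 29.6 to 177 CPM among the GFP controls, wider than among the gain libraries (48.2 to 68.9 CPM).

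Of 14698 genes tested in sorted cells, edgeR called 2, and 1264 had an unadjusted p under 0.05. Besides L3mbtl3, the processed pseudogene Rps2-ps13 (X chromosome, 52898588 to 52899469) fell from 71.5 ± 45.1 to 0.164 ± 0.0685 CPM (n = 3 each, edgeR adjusted p = 0.0175), with 815, 995 and 2452 counts in the GFP controls and 3, 5 and 2 in the gain libraries. A pseudogene of Rps2 by its name, it is uncertain, since both can share reads. Rps2 went the other way, with 1230, 1823 and 1750 counts in the GFP controls and 2095, 2297 and 2278 in the gain libraries. Whether reads were assigned differently between Rps2 and Rps2-ps13 was not tested. The call of Rps2-ps13 was lost without GFP control replicate 2 (edgeR adjusted p = 0.0930) and without each gain library (0.309, 0.0868 and 0.176). Its fold change ran from -9.06 to -8.05 (log2) with a library left out. The call was also lost with a term for embryo sex, where the 1 gene called had risen. Apoe, a lipoprotein made by glia and macrophages, was not called, at 11.8 ± 2.32 CPM against 26.6 ± 4.30 (n = 3 each), with a fold change of -1.18 (SE 0.196, edgeR adjusted p = 0.457). Sh3bgrl2 stood at 0.66 (SE 0.0989), the noncoding gene 4933404O12Rik at -1.91 (SE 0.238), Gm37814 at 1.44 (SE 0.204), Gm42993 at 1.12 (SE 0.179) and the pseudogene Hmgb1-ps7 at -1.04 (SE 0.150), none of them called either. Sycp2l, a synaptonemal complex gene, had 2, 0 and 0 counts in the GFP controls and 41, 37 and 34 in the gain libraries. Gm9008 had 0 counts in each GFP control and 68, 32 and 24 in the gain libraries, and among E12.5 libraries 84 counts in the wild-type and at most 1 elsewhere. The number of called genes rested on single libraries, being 415 without GFP control replicate 1, 0 without GFP control replicate 2 (693 at an unadjusted p under 0.05), 1 without gain replicate 1, 6 without gain replicate 2 and 1 without gain replicate 3. DESeq2 called 122 genes, voom with quality weights 2120 and edgeR on all 11 libraries in a single fit 97.

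The other lists tested in sorted cells did not pass camera in the main fit and held no member called over all genes there. Other settings called some of them lower: ventral telencephalon, astrocyte and oligodendrocyte, erythroid, meningeal and G2 and M phase lists with the replicate number as a block, all of these but the ventral list with DESeq2, and all but the erythroid and meningeal lists with voom and quality weights. Without GFP control replicate 3 the apical progenitor, intermediate progenitor, Notch, Cajal-Retzius and choroid plexus lists were among those called lower and the pan-neuronal list was called higher, while without GFP control replicate 1 the apical list was called higher. Other leave-one-out fits called the astrocyte, erythroid or meningeal list lower, and the length offset in DESeq2 added the deep-layer list (lower) and mitochondrially encoded mRNAs (higher). Among cell types other than cortical neurons, medians (log2) and camera's adjusted p were -1.06 and 0.440 for ventral telencephalon and GABAergic neurons (16 of 16 lower), -1.42 and 0.115 for meninges and mesenchyme (Col1a2 -1.74), -0.94 and 0.165 for erythroid cells, -0.91 and 0.185 for astrocyte and oligodendrocyte lineages, -0.44 and 0.185 for choroid plexus, -0.48 and 0.357 for Cajal-Retzius cells and -0.31 and 0.454 for cortical hem and Wnt signalling. Adjusted over the list alone, Apoe was the only member called among these lists. For progenitors and neurons the values were -0.19 and 0.759 for apical progenitors (Lhx2 0.42), -0.03 and 0.759 for intermediate progenitors (Elavl2 0.30, Hes6 -0.32), -0.05 and 0.981 for proneural factors (Nhlh1 0.35), -0.12 and 0.998 for the Notch pathway, -0.08 and 0.759 for pan-neuronal genes (Dcx 0.35), -0.28 and 0.454 for deep-layer neurons (Ldb2 -0.66) and 0.00 and 0.652 for upper-layer neurons (Unc5d 0.37). For chromatin complexes they were 0.03 and 0.652 for PRC1 subunits (Phc2 -0.31, Phc3 0.48), 0.00 and 0.702 for PRC2 subunits, and 0.01 and 0.357 for the MBT-domain family (Phf20 0.28). The remaining lists gave -0.36 and 0.454 for G2 and M phase, 0.06 and 0.652 for immediate early genes, 0.09 and 0.596 for interferon response, -0.06 and 0.759 for p53 response, -0.07 and 0.454 for hypoxia and glycolysis, 0.04 and 0.454 for mitochondrially encoded mRNAs and -0.11 and 0.982 for histones. Camera's direction was up although median and mean were negative for the apical, proneural, pan-neuronal, upper-layer, p53 and histone lists, and up against a negative median for intermediate progenitors. It was up against a negative mean for PRC2 subunits, and for immediate early genes it was down, as was the mean, against a positive median. A fold change also went with gene length, with a Spearman correlation of 0.354 across 12631 coding genes, which are not independent replicates.

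**Figure D2:**
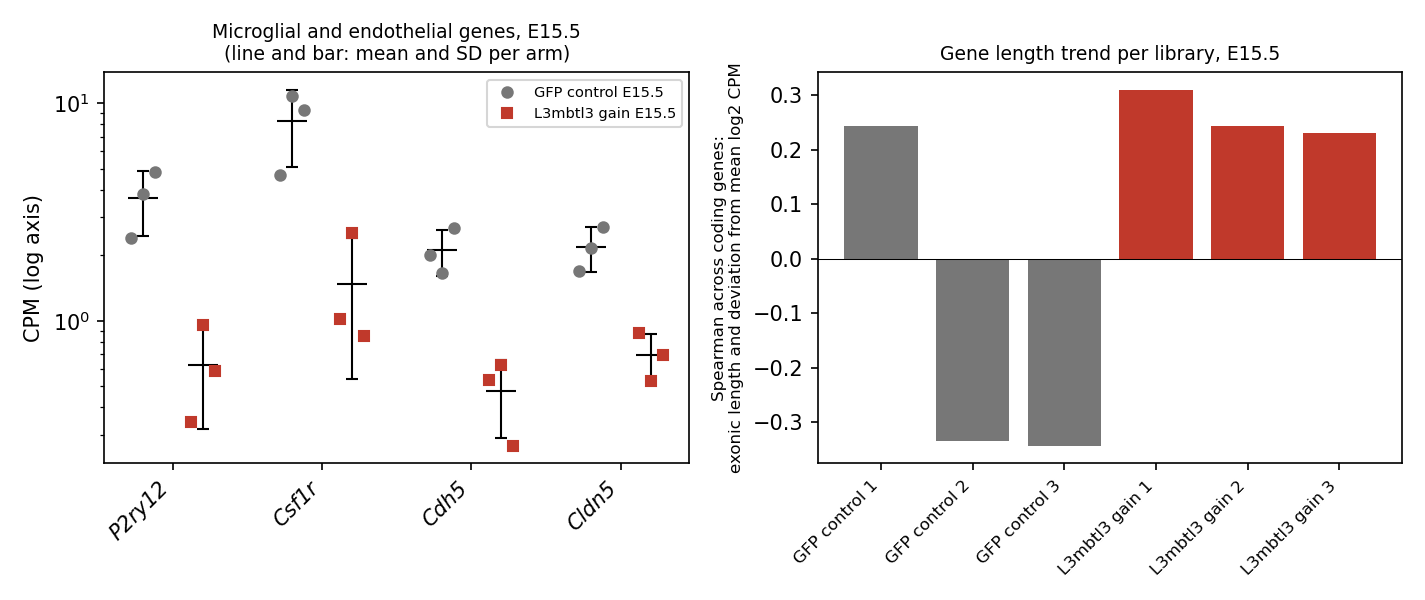
Left, CPM (log axis) of microglial and endothelial genes in each E15.5 library, with mean and SD per arm. Right, per library, the Spearman correlation across 12631 coding genes between exonic length and the deviation from the gene's mean log2 CPM. The markers are lower in all gain libraries, and GFP control replicate 1 shares the sign of the gain libraries while the other GFP controls have the opposite sign.

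In the E12.5 tissue, the lists of choroid plexus, intermediate progenitor, proneural and pan-neuronal genes were lower in the libraries labelled knockout, in which L3mbtl3 itself was not lower, while the Notch, cortical hem and ventral telencephalon lists were higher, by camera with a preset correlation but in no case with an estimated one. Of 16361 genes tested, edgeR called 1213, of which 594 rose and 619 fell. Of 11 choroid plexus genes 8 fell, with a median of -0.77 (log2), and the same number fell adjusted over the list alone, where 1 rose. Kcne2, a potassium channel subunit, fell from 24.2 ± 2.15 CPM in the controls (n = 3) to 6.11 ± 0.0207 (n = 2), a fold change of -1.98 (SE 0.108, edgeR adjusted p = 2.77e-06). The serotonin receptor Htr2c (-1.61, SE 0.101), the water channel Aqp1 (-1.37, SE 0.140) and the chloride channel family member Clic6 (-0.70, SE 0.0587) also fell. Camera called the list lower with an adjusted p = 5.24e-10, or adjusted p = 0.165 with an estimated correlation. Choroid plexus is an epithelium beside the cortical hem rather than cortex, and its genes were measured in all 5 libraries.

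Intermediate progenitor, proneural and pan-neuronal genes were lower together in the libraries labelled knockout. The intermediate progenitor and proneural lists share members, Eomes and Neurod4 among them, so their results are not independent. Of 16 intermediate progenitor genes 7 fell and 1 rose (10 and 1 adjusted over the list alone), with a median of -0.27. Eomes fell from 242 ± 5.37 CPM (n = 3) to 187 ± 0.519 (n = 2), or by 0.38 on the log2 scale (SE 0.0360, edgeR adjusted p = 0.000146). The RNA-binding protein gene Elavl2 (-0.36), the somatostatin receptor Sstr2 (-0.56) and Rhbdl3 (-0.37) fell with it. Of 21 proneural factors and reported targets 9 fell and 1 rose (14 and 1 adjusted over the list alone), with a median of -0.26. Neurod1 (-0.44, SE 0.0634), Neurod4 (-0.79, SE 0.124) and Bhlhe22 (-0.59, SE 0.0765), basic helix-loop-helix factors of differentiating neurons, fell. Of 22 pan-neuronal genes 8 fell (11 fell and 1 rose adjusted over the list alone), with a median of -0.22, such as Elavl4 (-0.31) and Rbfox3 (-0.37), both RNA-binding proteins of neurons, and the adhesion molecule L1cam (-0.38). Camera gave adjusted p = 8.44e-06 for intermediate progenitors, 5.34e-08 for the proneural list and 5.72e-06 for pan-neuronal genes. With an estimated correlation the adjusted p values were 0.165, 0.165 and 0.617. The calls of Rbfox3 and L1cam were lost when a library was left out (highest edgeR adjusted p 0.0749 and 0.182), Rbfox3 without knockout replicate 2 or the wild-type, L1cam without heterozygote replicate 2 or either library labelled knockout. The risen member of the intermediate progenitor list, Chd7 (0.18), was named after its value was seen. In the same libraries choroid plexus genes were lower (median -0.77) and ventral telencephalon genes higher (median 0.80).

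While Eomes was called, 9 of the fixed neurogenesis genes were not called at E12.5 by edgeR. Neurog2 measured 196 ± 24.7 CPM in the libraries labelled knockout (n = 2) against 234 ± 10.6 (n = 3), at -0.25 (SE 0.0774, edgeR adjusted p = 0.111), and Neurog1 stood at -0.26 (0.104). Not called either were Tbr1 at -0.14 (edgeR adjusted p = 0.0569), Sox2 at 0.28 (0.0526), Pax6 at 0.01 (0.935), Hes1 at 0.21 (0.261), Hes5 at 0.12 (0.347), Dll1 at 0.04 (0.666) and Rbpj at -0.14 (0.865).

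The Notch, cortical hem and ventral telencephalon lists were called higher in the libraries labelled knockout, with few called members in each. Of 22 Notch pathway genes 3 rose (4 adjusted over the list alone), with a median of 0.09. Jag2, a Notch ligand, rose from 18.7 ± 0.314 CPM (n = 3) to 47.4 ± 4.05 (n = 2), at 1.35 (log2, SE 0.0711, edgeR adjusted p = 2.77e-06). The ligand Jag1 rose by 0.35 (SE 0.0624) and the effector Heyl by 0.36 (SE 0.0853). Of 20 cortical hem and Wnt genes 3 rose (6 adjusted over the list alone) and 18 were higher, with a median of 0.19, led by the ligand Wnt8b (0.61, SE 0.0953), the homeobox gene Msx1 (0.33) and the Wnt potentiator Rspo2 (0.41). Of 17 ventral telencephalon and GABAergic genes 3 rose and 1 fell (10 and 1 adjusted over the list alone), with a median of 0.80. The homeobox genes Gsx2 (1.16), Dlx2 (0.85) and Dlx5 (0.83) rose, while Sst, the neuropeptide of an interneuron class, fell (-2.17). Dlx2 was at 14.4 ± 0.143 CPM there (n = 2) and 8.17 ± 2.35 in the controls (n = 3). Camera's adjusted p was 0.0210 for Notch, 9.05e-05 for hem and Wnt and 3.75e-06 for ventral genes. With an estimated correlation the adjusted p values were 0.617, 0.523 and 0.523. The Notch and ventral calls were lost with all 11 libraries in a single fit. The Notch call was also lost without knockout replicate 2 (median 0.01), without the wild-type (0.07) and with the replicate number as a block (0.07). It was lost with a term for embryo sex too (0.01). Like the fit without knockout replicate 2, that term leaves the effect to knockout replicate 1. The hem median was 0.05 without knockout replicate 2 and 0.30 without knockout replicate 1. The ventral median was 0.51 without knockout replicate 1. The calls of Heyl, Msx1, Rspo2, Gsx2, Dlx2 and Dlx5 were each lost when a library was left out, with highest edgeR adjusted p values of 0.0927, 0.0614, 0.153, 0.182, 0.187 and 0.142.

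Among MBT-domain genes and reported partners of L3mbtl3, few members were called. Of 15 MBT-domain family members and reported partners 3 rose and 1 fell (6 and 1 adjusted over the list alone), with a median of 0.07. With a library left out that median ran from 0.053 to 0.155. The MBT-domain genes Sfmbt2 (1.67, SE 0.149) and Sfmbt1 (0.34, SE 0.0507) and the chromatin gene Samd1 (0.95, SE 0.107) rose, and Phf20l1 (-0.26, SE 0.0515) fell. Samd1 measured 118 ± 11.6 CPM (n = 2) against 60.7 ± 7.48 (n = 3, edgeR adjusted p = 0.00381). Camera gave an adjusted p = 0.0144, or adjusted p = 0.451 with an estimated correlation. Without knockout replicate 2 the calls of the list, Samd1 and Phf20l1 were lost. The list also missed the threshold with all 11 libraries in a single fit and with a term for embryo sex. That term leaves the effect to knockout replicate 1, as does the fit without knockout replicate 2. Ribosomal protein genes were called lower as a list with a median of -0.03 and 61 of 78 lower, although 0 members were called (camera adjusted p = 0.0329, edgeR for the members, or adjusted p = 0.853 with an estimated correlation). DESeq2 did not call this list (adjusted p = 0.0848), and neither did the fits with all 11 libraries, with the replicate number as a block, without the wild-type (median -0.02) and without knockout replicate 1, where the median was 0.01. None of the 9 lists called at E12.5, and none of the 4 called at E15.5, was called by camera with an estimated correlation. By fry, choroid plexus (adjusted p = 0.0116), intermediate progenitors (0.0116) and the proneural list (0.0168) were called at E12.5, and endothelial cells (0.0265) at E15.5.

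**Figure D3:**
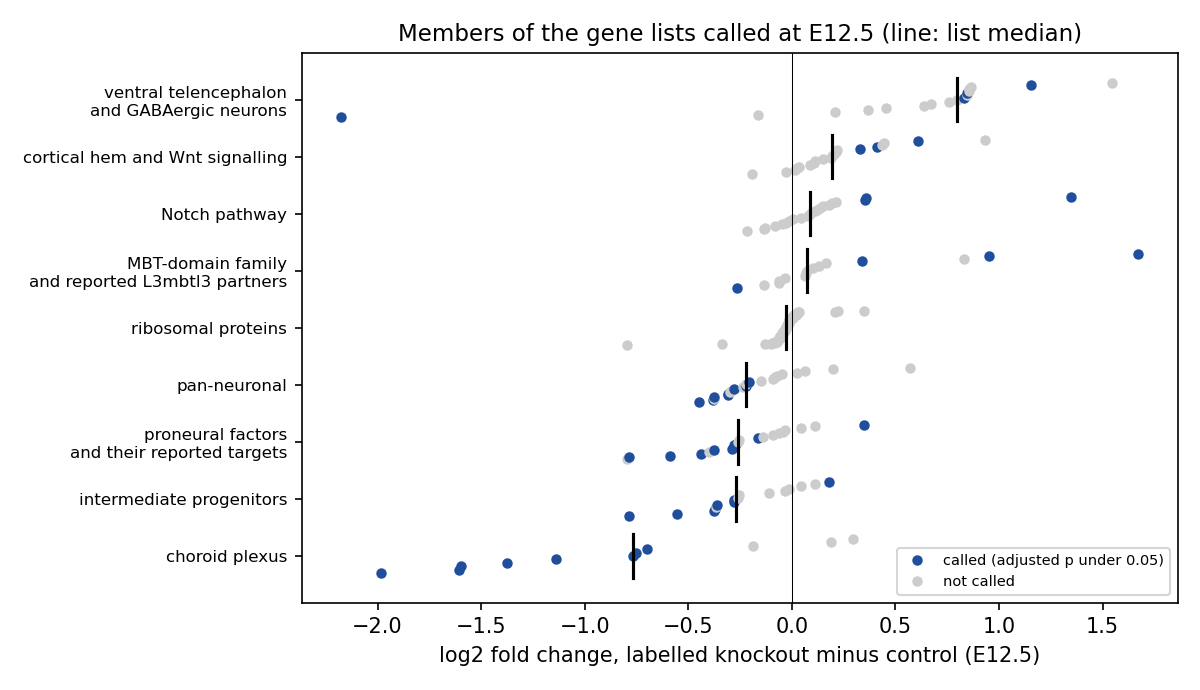
Log2 fold change of the members of the 9 lists called at E12.5, labelled knockout minus control. Each point is a gene, blue where edgeR called it, and the line is the list median. Medians run from -0.77 for choroid plexus to 0.80 for ventral telencephalon genes.

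The largest changes below are those among called coding genes with a mean log2 CPM of at least 1 and no overlap between the arms, and called genes outside these limits had changes as large. In the libraries labelled knockout Serpinb1b, a protease inhibitor with close paralogs, fell by 2.42 on the log2 scale, Dnah3, an axonemal dynein heavy chain, by 2.29, Ccdc180 by 2.00, Kcne2 by 1.98, 2810459M11Rik by 1.96, the myosin-binding protein gene Mybpc1 by 1.88, the adenylate kinase Ak7 by 1.86 and Slc4a5, a bicarbonate cotransporter of the choroid plexus, by 1.81. Within the same limits the largest rises were in Tmem132e (1.76), the chaperone gene Clgn (1.69), Ugt8a, a galactosyltransferase for myelin lipids (1.68), the synaptic organiser Cbln1 (1.67), Sfmbt2 (1.67), Fam189a1 (1.57), Trim71, an RNA-binding ubiquitin ligase of early embryos (1.54), and the lipid transporter Abca7 (1.47). Abca7 rose from 19.9 ± 0.292 CPM (n = 3) to 55.0 ± 0.286 (n = 2, SE of the fold change 0.0593, edgeR adjusted p = 3.44e-07). EdgeR's adjusted p for these 16 genes ran up to 0.00687 for Ccdc180. Each was lower or higher in both libraries labelled knockout than in all 3 controls.

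**Figure D4:**
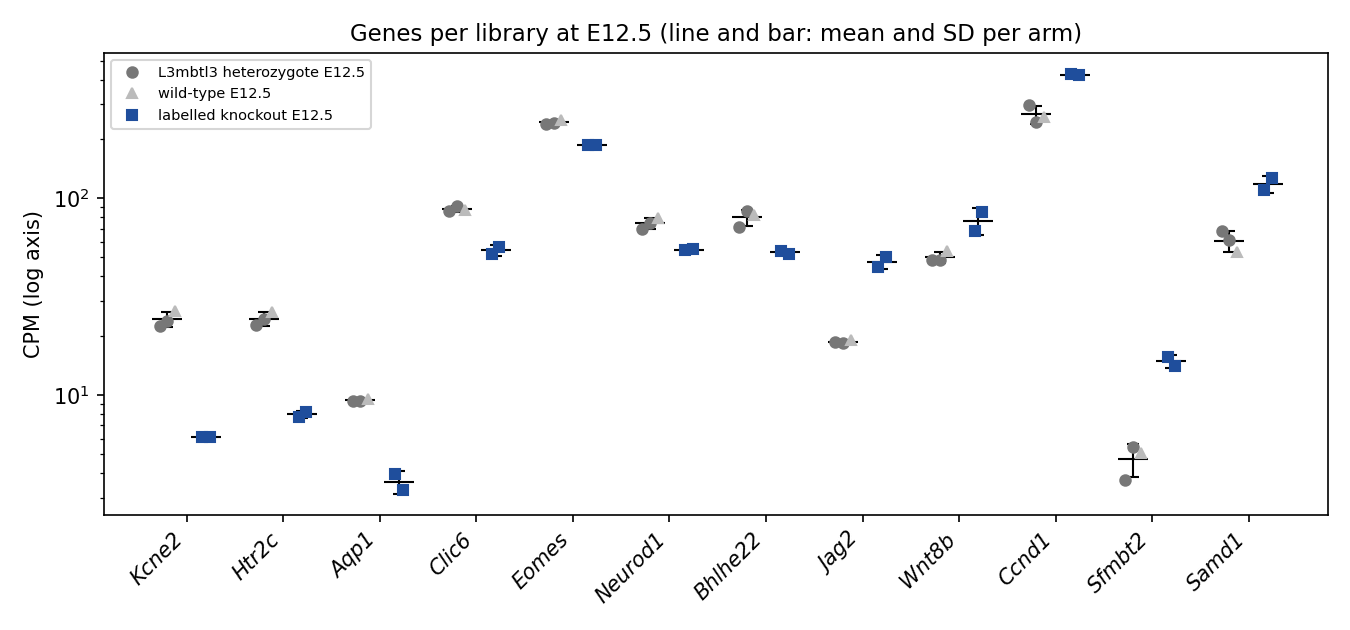
CPM per library (log axis) at E12.5 for genes of the choroid plexus, neurogenesis, Notch, Wnt, cell cycle and MBT groups. Points are libraries, and the line and bar give the mean and SD per arm. Kcne2, Htr2c, Aqp1, Clic6, Eomes, Neurod1 and Bhlhe22 are lower and Jag2, Wnt8b, Ccnd1, Sfmbt2 and Samd1 higher in both libraries labelled knockout.

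Other lists at E12.5 did not pass camera, although some of their members were called. In the apical progenitor list (median 0.02, camera adjusted p = 0.823) 5 of 24 genes fell and 1 rose, with the glial transporter Slc1a3 (-0.33), the glycolytic enzyme Aldoc (-0.99) and the fatty acid binding protein Fabp7 (-0.24) lower and Emx2 higher (0.29). The other fallen members, Tnc (-0.45) and Cdon (-0.22) here and Crym (-0.76) among deep-layer genes, were named after their values were seen. Of 15 deep-layer genes 3 fell and 2 rose (median -0.14, 0.133), with Nfib (-0.32) and Sox5 (-0.36) among the former and Tle4 (0.25) and Foxp2 (0.32) as the latter, and of 13 upper-layer genes Cux2 (0.87) and Cux1 (0.21) rose (median -0.07, 0.823). Cajal-Retzius genes (median 0.05, 0.473) held Ndnf, which rose (0.82), and Nhlh2, which fell (-0.29), and the astrocyte and oligodendrocyte list (median -0.08, 0.678) held Olig1, which rose (1.59), and Apoe, which fell (-0.76). The cyclin gene Ccnd1 rose (0.67, SE 0.0786) as the only called gene of G1 and S phase (median 0.02, 0.327), and the mitotic kinase Plk1 (0.27) as that of G2 and M phase (median 0.03, 0.0995). Bcor (0.24) and Cbx6 (0.19) rose among 22 PRC1 subunits (median 0.07, 0.0673), no PRC2 subunit was called (median 0.04, 0.216, Phf19 at 0.46 with the smallest p), and of 24 developmental regulators of other regions Pax7 (1.27) and Prdm12 (0.72) rose (median 0.08, 0.411). Adjusted over the list alone, calls numbered 9 for apical progenitors, 10 for deep-layer, 3 for upper-layer, 2 for Cajal-Retzius, 5 for astrocyte and oligodendrocyte, 1 for G1 and S phase, 1 for G2 and M phase, 3 for PRC1, 1 for PRC2 and 2 for developmental regulators.

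Among the remaining lists at E12.5, markers of other cells were mostly not called. Lyz2 fell (-1.01) and Fcrls rose (0.53) among 16 microglial genes (median -0.06, camera adjusted p = 0.606), no endothelial gene of 17 was called (median 0.05, 0.0509, Plvap at 0.53), and Gata1 rose (1.20) among 13 erythroid genes (median 0.10, 0.375). In meninges and mesenchyme (median 0.09, 0.606) Ogn (-0.43) and Slc6a13 (-1.01) fell and Prrx1 (0.21) rose. Of 19 p53 response genes 4 rose, Pmaip1 (0.75), Sesn2 (0.45), Zmat3 (0.28) and Bbc3 (0.55), and 1 fell (median -0.06, 0.823). Jund (0.18) and Klf6 (0.22) rose among immediate early genes (median 0.15, 0.0673), and Vegfa (0.21) and Pfkl (0.19) rose while Ddit4 (-0.28), Pdk1 (-0.30) and Ndrg1 (-1.15) fell in the hypoxia and glycolysis list (median -0.04, 0.267). Ndrg1, and Sesn1 (-0.24), the p53 response gene that fell, were named after their values were seen. Interferon response (median -0.15, 0.473, Oasl2 at -0.89), mitochondrially encoded mRNAs (median 0.05, 0.0712) and histones (median -0.03, 0.903) held no called gene. Adjusted over the list alone, calls numbered 3 for microglia, 2 for endothelial cells, 1 for erythroid cells, 6 for meninges, 6 for p53 response, 2 for immediate early genes, 6 for hypoxia and 0 for the other 3 lists. Camera's direction was down against a positive median for apical progenitors and against a positive mean for the astrocyte and p53 lists, and up against a negative median for upper-layer and histone genes and against a negative mean for upper-layer and meningeal genes.

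The number of genes called in the loss comparison differed with the libraries that entered it. Of its 81 named genes that edgeR called, 43 were called without each library in turn, and 33 calls were lost without knockout replicate 2, 27 without the wild-type, 23 without heterozygote replicate 2, 14 without heterozygote replicate 1 and 12 without knockout replicate 1. Outside the called lists, Slc1a3, Aldoc, Fabp7, Nfib, Cux2, Ndnf, Olig1, Apoe, Pmaip1, Ddit4 and the 16 genes with the largest changes were called in each of these fits, and the other called members that the rule named were not. The count of 1213 became 1785 without knockout replicate 1, 1059 without heterozygote replicate 1, 673 without heterozygote replicate 2, 658 without knockout replicate 2 and 603 without the wild-type, and 15 with all 11 libraries in a single fit.

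Set against each other, the fold changes of the comparisons were weakly correlated across genes. If more and less L3mbtl3 had opposite effects, fold changes would be negatively correlated, with the reservation that L3mbtl3 was not lower in the libraries labelled knockout. The Pearson correlation was 0.021 and the Spearman correlation -0.119 across 14305 genes tested in both, and genes are not independent replicates. Genes that fell at E12.5 had a median of 0.05 (log2) in the gain comparison, where 45.1% of 510 were lower, and as a set they were higher there (camera p = 0.000818, or p = 0.00395 with an estimated correlation, fry p = 0.00825). Genes that rose at E12.5 had a median of -0.07 there, with 59.1% of 552 lower (camera p = 0.350, p = 0.750 with an estimated correlation, fry p = 0.801). All 14698 genes tested in the gain comparison had a median of -0.03, so most of them were lower too. The genes called in sorted cells were too few to test as sets. L3mbtl3 was the only gene called in both, and it rose in both. A test of the difference between the gain effect and the control minus knockout effect, in a fit of all 11 libraries over 17060 genes, called 7 genes by edgeR, among them L3mbtl3 and the coding genes Abca7, Apoe and Car12. Apoe was lower in both comparisons, at -1.18 in sorted cells, where it was not called, and at -0.76 in the libraries labelled knockout, where it fell.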

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

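The tests for embryo sex, for a swap of libraries and of other splits of the samples were chosen after the loss result was seen, and the test of the difference of effects was fixed earlier. That test, edgeR on all 11 libraries with Benjamini-Hochberg adjustment over 17060 genes, found 7 genes whose gain effect differed from the control minus knockout effect, both written as more minus less L3mbtl3 by the labels. The difference was 4.75 (log2) for L3mbtl3 itself, which rose in both comparisons. For the pseudogene Rps2-ps13 it was -8.73, with counts of 2281 to 3939 in the E12.5 libraries, 815 to 2452 in the GFP controls and 2 to 5 in the gain libraries. For Abca7, a lipid transporter, it was 1.82 (adjusted p = 0.0168), and for Gm2694, a noncoding gene that rose in the libraries labelled knockout, 2.81 (adjusted p = 0.0164). The difference was -1.95 for Apoe (adjusted p = 0.0353) and -2.22 for the carbonic anhydrase Car12 (adjusted p = 0.0425). Apoe and Car12 fell in the libraries labelled knockout and had negative fold changes in sorted cells (-1.18 and -1.04), where edgeR called neither. Since L3mbtl3 was not lower in the libraries labelled knockout, the sign of each difference follows the labels, not the measured level. DESeq2 found 198 such genes.

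The first pattern weighed is that L3mbtl3 was not lower in the libraries labelled knockout while 1213 genes separated them from the controls. A swap of a library with a control is argued against, since no other split of the 5 libraries called more than 3 genes, and a swap with a sample outside the 5 was not tested. Embryo sex as the whole source is argued against: it would make the 4 male libraries alike, but splits that put knockout replicate 2, the only female library, with a male control called at most 1 gene, against 1213 when it was put with knockout replicate 1. With a sex term, as with the 4 male libraries alone, the knockout effect rests on knockout replicate 1, so sex as part of the source stays open. With 10 splits of 2 against 3 libraries, of which 1 gave as many genes, the splits are too few for a share under 0.05, with 1213 genes for the real split and 3 for the highest other. What stays open is a label that is wrong for both libraries, an allele that leaves transcript counts in place, and any litter or batch shared by both, none of which was tested. A biological difference by genotype is open in the same way.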

How the results depend on the processing

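The term for embryo sex, the male libraries, the surrogate variable and the exonic length offsets were chosen after seeing the data, and for the values below the cause was not tested unless it is given. With a sex term the arm effect rests on gain replicate 2 or on knockout replicate 1. At E12.5 it is thus no separate check from the fit without knockout replicate 2. In sorted cells edgeR called 2 genes; DESeq2 called 122, voom with quality weights 2120, and all 11 libraries in 1 fit 97. A sex term or male libraries only (fewer samples) left 1 gene each, a surrogate variable gave 1342, the length offset without GFP control replicate 1 gave 8 and the length offset in DESeq2 83. With a library left out the count ran from 0 (without GFP control replicate 2) to 415 (without GFP control replicate 1). The 4 lists called became 8 with DESeq2, 7 with voom, 2 with a sex term, 2 with male libraries only, 10 with the length offset in DESeq2, 0 with an estimated correlation, 1 with fry, and 3 to 13 with a library left out (13 without GFP control replicate 3). Medians turned direction in apical progenitors (-0.53 to 0.23 with a library left out, called in opposite directions without GFP control replicates 3 and 1), intermediate progenitors (-0.19 to 0.11), G1 and S phase (-0.55 to 0.0434, and 0.0171 with the length offset and without GFP control replicate 1) and, by camera's direction, ribosomal proteins (-0.24 to -0.00508).

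In the E12.5 tissue, 1213 called genes became 2266 with no count filter (more genes tested), 15 with all 11 libraries in 1 fit, 205 with a log2 fold change of at least 1, 176 with mutant alleles as a linear term, 654 with a sex term, and 603 to 1785 with a library left out. The balance of directions also moved. Of the 205 genes 59 rose and 146 fell, of the 176 genes 121 and 55, and of the 15 genes 12 and 3. The 9 lists became 14 with no filter, 5 with all 11 libraries, 0 with an estimated correlation and 3 with fry, and the ribosomal median ran from -0.0630 to 0.00822 with a library left out, turning up without knockout replicate 1. The L3mbtl3 rise at E12.5 lost its call at 0.26 with all 11 libraries, at 0.27 when a log2 fold change of at least 1 was asked, at 0.28 with alleles as a linear term and at 0.23 with a sex term, and ran from 0.23 to 0.30 with a library left out. In sorted cells the L3mbtl3 rise ran from 4.31 to 4.67 with a library left out and lost its call without GFP control replicate 2. The Pearson correlation of gain and loss was 0.174 for genes with a mean log2 CPM of at least 3 and -0.0808 without L3mbtl3, sex-linked genes and markers of other cells, and the Spearman correlation -0.162 and -0.122. DESeq2 found 198 differences of effect, against 7 by edgeR. As sets, the 200 genes with the smallest p per direction in sorted cells were tested at E12.5, with camera p = 2.22e-07 (lower) for those higher and p = 0.192 for those lower, or p = 0.214 and p = 0.220 with an estimated correlation.

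Whether replicate numbers pair the samples was not settled. In sorted cells deviations of same-numbered libraries correlated at 0.180, 0.00998 and 0.257, and those of differently numbered libraries at -0.271 to 0.115. A shared batch by number thus stays open there. Deviations were taken from each group's mean, so these values are not independent. Heterozygote and knockout libraries of the same number correlated at 0.0119. With 2 libraries per group, the value for different numbers (-0.0119) is fixed as the opposite of that, so it adds no comparison. With the replicate number as a block, sorted cells gave 3 genes and 9 lists, and heterozygote against knockout gave 319 genes and an L3mbtl3 fold change of 0.28, not called. Over the other results and settings, 1424 named-gene values in sorted cells stayed on their side of the threshold, 111 gained and 8 lost the call, and at E12.5 1381 stayed, 39 gained and 415 lost it. For lists the numbers were 557, 37 and 17 in sorted cells and 499, 23 and 28 at E12.5, and 5 and 1 list values turned direction with a call in at least 1 of the 2 fits. Of those that stayed, 30 and 7 gene values and 68 and 20 list values changed sign without being called in either fit. In the simulation, which had no trends shared between genes, changes of 0.5 (log2) were recovered for 3 of 67 genes in the gain design by edgeR. In the loss design 57 of 67 were recovered.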

Other observations

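The gene groups in the first paragraph were picked after their values were seen, so their counts describe these genes and test nothing, and the tests in this part except the length correlation within non-neuronal lists were chosen after the results were seen. Genes of motile cilia, the beating cilia of choroid plexus and ependymal cells, were lower in the libraries labelled knockout, where L3mbtl3 was not lower. The 86 tested members of the picked families also held Ift genes, none of which was called, and Spag genes such as Spag5 and Spag9. Not all of them are therefore genes of motile cilia. Of the 86 members 29 fell and 0 rose by edgeR, with a median of -0.42 (log2). The axonemal dyneins Dnah6 (-1.47) and Dnah9 (-1.24), the radial spoke gene Rsph1 (-0.92) and Cfap44 (-1.09) were among them. In sorted cells the 54 tested members had a median of 0.00. Dnah6, Rsph1, Cfap44 and most of the other genes that fell at E12.5 did not pass the count filter there. That median therefore does not describe the fallen genes. Among picked RNA-binding and growth genes typical of earlier development most were higher, with 8 of 12 risen and 1 fallen (Crabp2) by edgeR and a median of 0.51. Lin28a (1.64), Lin28b (0.86) and Hmga1 (0.67) rose, as did Igf2bp1 (0.31), Igf2bp2 (0.35) and Igf2bp3 (0.25). Among picked genes of later progenitors and glia most were lower, with 12 of 22 fallen and 0 risen by edgeR and a median of -0.33, led by the proteoglycan gene Bcan (-1.57) and by Ndrg2 (-1.11), Aldoc (-0.99) and Apoe (-0.76). Samd3, whose annotated span (chromosome 10, 26229707 to 26272172) lies next to L3mbtl3, rose by 1.00 (SE 0.142, edgeR adjusted p = 0.00189) in the libraries labelled knockout, from 5.03 to 10.2 CPM.

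That the lists of choroid plexus and intermediate progenitor genes, fixed beforehand, were lower and the cortical hem list higher at E12.5 was weighed against 3 explanations. Fewer choroid plexus cells alone would move the genes of other cells alike. The intermediate progenitor list had a median of -0.271 (upper quartile -0.0279) and the cortical hem list a lower quartile of 0.0727. That account alone leaves this gap unexplained. The gap is part of the pattern itself and was known when the rule was set, so it is no separate test. Medial tissue left out at dissection would lower cortical hem genes too. These had a median of 0.193 with 18 of 20 higher, and a median of 0.05 without knockout replicate 2. For this list, which also holds general Wnt genes, that argues against hem and choroid plexus being left out together. The rule was set after these values were seen, and other differences of dissection were not tested. Younger embryos in the libraries labelled knockout may account for the pattern and cannot be told apart from genotype: the ratio of adult-type to embryonic beta-globin was lower in both than in each control, by a mean of -0.523 (log2, exact one-sided permutation p = 0.1, the smallest that 10 splits allow), while the alpha-globin ratio overlapped (-0.146, exact p = 0.3). A biological difference by genotype stays open and untested.

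In sorted cells, longer genes were higher in the gain libraries, and GFP control replicate 1 shared that trend (Spearman of 0.243 between exonic length and deviation, against -0.335 and -0.343 in the other GFP controls and 0.230 to 0.309 in the gain libraries). A length trend as the whole source of the 122 genes that DESeq2 called is argued against, since their median absolute fold change was 0.645 (SE 0.157) without and 0.565 (SE 0.163) with a per-library length offset, with which 83 genes were called, 68 of them among the 122. Of the 122 genes 78 rose and 44 fell, and of the 83 genes 43 rose and 40 fell. The length trend as a source of part of these calls thus stays open. Without GFP control replicate 1, 415 genes were called, and with the offset 8, of which 7 were among the 415. The median absolute fold change of the 415 went from 0.591 (SE 0.0990) to 0.388 (SE 0.0900), while 407 kept their sign and 335 an unadjusted p under 0.05. Of the 408 that lost the call, 348 had a smaller fold change and 121 a larger SE; 275 had a p above the highest called before (0.00138), and the other 133 fell short of the stricter cutoff that adjustment sets when fewer p values are small. How far a technical length trend may account for the 415 cannot be told apart from an effect of L3mbtl3. Neuronal maturation through long neuronal genes stays open as well, since within 10 non-neuronal lists the correlation of length and fold change was 0.159 over 136 genes (permutation p = 0.0648), between the values that either account would give. With 10 splits of the 6 libraries, of which 1 gave as many genes, the splits are too few for a share under 0.05, with 2 genes for the real split and 1 for the highest other.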
